A study of Mus musculus with 2 samples.

How the data were processed

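H3K27ac ChIP-seq had been done on midbrain of mouse embryos of the B6NCrl strain at embryonic day 10.5, as 2 biological replicates of 69 and 51 pooled embryos of both sexes, per the labels. The 4 deposited files used here are peak lists in narrowPeak format on the mm10 assembly, per the labels and the text listings deposited with the samples. Peaks had been called per sample and on pooled samples: per those deposited listings, the list of replicate 1 was made from 1 alignment and 2 control files, that of replicate 2 from 1 alignment and 1 control file, and the pooled list from 2 alignments and 2 control files. The replicated list was derived from the other 3 peak lists. The aligner, the peak caller, its version and threshold, and the rule of the replicated list are not given in the sources used here. Peak lists hold no read counts, so the depth of the samples was unknown and no test on reads was possible.

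Each peak carries a score, an enrichment, a p value and a q value from the authors' peak caller; the p value was not used. The display score of the deposited lists is scaled within a list and was not used. The enrichment is the authors' signal value, a ratio of the peak over its control, as deposited. The -log10 q value is also the authors' and was deposited with each peak. The enrichment served to describe, rank and filter peaks within a list. It was also tested once, between promoter peaks of the X chromosome and of autosomes within the replicated list. No test compared it between lists, because lists called separately share no scale. The lowest -log10 q was 0.587 in replicate 1 and 0.518 in replicate 2, so the deposited lists hold weak peaks, and 79.8%, 71.2%, 87.1% and 98.9% of peaks reached 2 in the replicate 1, replicate 2, pooled and replicated lists. The position of each summit within its peak was taken from the deposited lists.

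Coordinates are 1-based on mm10, with the mm10 sequence and the GENCODE M21 annotation; no peak lay beyond the end of its chromosome. Peaks off the assembled chromosomes (10, 10, 12 and 9 per list) were counted in the sizes of the lists and in the match of replicated with pooled peaks, and left out of all other comparisons. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, bedtools 2.31.1, samtools 1.23.1 and matplotlib 3.10.9 were used, with random seed 7.

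A peak counted as shared when at least 50% of its length was covered by peaks of the other replicate. The chance level came from 100 shufflings of positions within chromosomes. Shares have 95% Clopper-Pearson intervals, which cover counting error over peaks only and not the difference between embryos. With 2 replicates, means are given with the SD over the replicates' own lists. A promoter was the 1 kb on either side of any annotated start site of a protein-coding gene's transcripts for gene lists, and of any gene's for locations; a peak outside promoters counted as exonic, intronic or intergenic, in that order. Promoter peaks of the genes of a list were compared with all other protein-coding genes by a two-sided Fisher's exact test, where odds ratios have 0.5 added to each count if a count is 0, and with 10000 random lists matched on quintile of promoter CpG observed over expected. CpG was measured within 1 kb of the gene's own 5′ end, so a gene with its peak at another start site was not matched on that promoter. The sequence under peaks within 50 kb of each gene's 5′ end was compared as the mean of log2(bp + 1) with 100000 random lists of the same size in a two-sided permutation test. On this scale members with 0 bp weigh heavily. Adjusted p values are Benjamini-Hochberg values over the 14 lists, with a threshold of 0.05.

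The 14 lists, fixed before the data were examined, hold 301 genes, all found in the annotation: midbrain and isthmus patterning, midbrain floor plate and dopaminergic, neural progenitor, neurogenesis and early neuron, forebrain and eye patterning, Hox clusters and hindbrain, neural crest and head mesenchyme, endothelial, erythroid, microglia and macrophage, surface ectoderm, heart and skeletal muscle, liver, and housekeeping. Named genes followed a rule fixed at the same time: the 3 members of each list with the most peak sequence within 50 kb, up to 3 members in alphabetical order with no replicated promoter peak, the 20 stitched domains with the most covered sequence, the 10 widest peaks, the 5 strongest peaks of each replicate that the other did not touch, and the 10 genes with the most peak sequence within 50 kb. Genes named as examples of a list whose members all had a promoter peak, and Shh, were taken from the lists after their values were seen. Domains were peaks at most 12.5 kb apart, and their ranking has no test.

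For motifs, 18 consensus sequences fixed before the data were examined were searched on both strands in the 200 bp around the summits of distal peaks, which have no start site within 2.5 kb, and in a window of the same size 2 kb from the peak edge and outside any peak. Presence was compared by a two-sided exact McNemar test over pairs, with Benjamini-Hochberg adjustment over the 18 motifs. The reversed, not complemented, consensus was searched in the same windows as a control of composition and is reported only for motifs whose reverse holds no CpG, a restriction chosen after the data were seen. The exception is SOX extended in windows matched on CpG. Of 61646 distal peaks 53807 had such a control window.

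The list test was tested on simulated data over the 21911 genes of the promoter comparison. Of 200 unchanged lists of 25 genes, 4% had a Fisher p under 0.05, and of 100 lists with a peak at 80% of genes against 50% of others, 95% did. In the data 65.5% of genes had a promoter peak, and the lists held 14 to 30 genes. The 95% therefore does not give the power for the lists that did not pass.

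Alternatives planned in advance were peaks with -log10 q of at least 2, the quartile of peaks with the highest enrichment, the pooled list, each replicate's own list, overlaps of at least 1 bp, 25% or a reciprocal 50%, promoters of 0.5 and 2.5 kb either side or the gene's own 5′ end alone, CpG-matched lists, windows of 20 and 100 kb, bp without the log, distal peaks alone, stitching of 5 kb or none, motif windows of 500 bp and control windows 5 kb away. Chosen after the data were seen were control windows matched on GC and CpG, the same with at most 10% repeat-masked bases in both windows, and lists with 1 member per 100 kb. Also chosen then were 9 further lists of 160 genes (WNT, FGF, Hedgehog, BMP, Notch and retinoic acid pathways, cell cycle and replication, synaptic genes of mature neurons, and glia), 73 further markers of mesenchyme, endothelium and surface ectoderm, 17 microRNA genes and a count of list members in the 500 domains with the most covered sequence.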

Results

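Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in midbrain dissected from mouse embryos at embryonic day 10.5. At this stage the midbrain is a neuroepithelium that is being patterned from the isthmus, its border with the hindbrain, and from the floor plate, and the first neurons are forming. There were 2 biological replicates, pools of tissue from 69 embryos (replicate 1) and 51 embryos (replicate 2) of both sexes. The labels give 1 group, so the comparisons are between the replicates, between the peak lists, and between gene groups and genomic locations within a list. The list of replicate 1 held 142842 peaks over 80.4 Mb and that of replicate 2 held 138556 peaks over 73.5 Mb, a mean of 140699 ± 3031 peaks (SD, n = 2) and 2.82% ± 0.177 of the genome. The list called on both replicates pooled held 178421 peaks, and the replicated list, on which the comparisons below rest unless another is named, held 86424 peaks over 82.0 Mb with a median width of 596 bp. Read depth was unknown, because peak lists hold no read counts.

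The replicates were compared first, to ask how far they placed H3K27ac at the same positions. Strong and promoter peaks were shared more often than weak and distal ones. Of the replicate 1 peaks at promoters, 78.6% were at least 50% covered by replicate 2 peaks, against 38.6% in introns and 42.6% between genes; of the replicate 2 peaks, 76.9%, 49.0% and 48.3% were covered by replicate 1. In the quartile of each list with the highest enrichment, 89.3% and 93.1% of peaks were shared, and in the lowest quartile 23.2% and 31.0%. Over whole lists, 47.1% of replicate 1 peaks (95% Clopper-Pearson interval 46.8 to 47.4) and 53.6% of replicate 2 peaks (53.3 to 53.9) were shared, against 2.78% ± 0.0513 and 3.09% ± 0.0488 (SD over 100 shufflings) when positions were shuffled within chromosomes. Shared sequence came to 53.0 Mb, which was 66% of the sequence in replicate 1 peaks and 72.1% of that in replicate 2 peaks. The share found depended on the overlap asked for: with at least 50% of both peaks of a pair required, it was 35.7% and 36.8%.

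Peaks without any counterpart had a median enrichment somewhat below that of their list. The strongest of them lay in the top quartile of enrichment, which began at 3.68 in replicate 1 and 4.07 in replicate 2. They stayed far below the highest enrichment of each list. In replicate 1, 60266 peaks (42.2%) were touched by no replicate 2 peak and had a median enrichment of 2.60; in replicate 2 these were 51817 peaks (37.4%), with a median of 2.74. The highest enrichment among them was 7.48 in replicate 1, at a promoter of non-coding transcripts on chromosome 3 (88203563 to 88208423) that lay 46.3 kb from the nearest protein-coding gene, Rhbg, an ammonium transporter. The next were intronic or intergenic, at X 169999204 near Gm21887, chromosome 13 29194314 (240.6 kb from Sox4, a transcription factor of early neurons), chromosome 5 31023280 near Atraid and chromosome 12 82369716 near Sipa1l1. Among the replicate 2 peaks that replicate 1 lacked, the highest reached 6.86 in an intron on chromosome 2 (65145792 to 65146339), 93.1 kb from Cobll1. Next came the promoter peak of Plbd1 on chromosome 6 (6.56), an intergenic peak near Vmn2r82 on chromosome 10 (6.40), and peaks 0.094 kb from Foxc1 on chromosome 13 (6.40), a forkhead gene of head mesenchyme, and 0.146 kb from Casz1 on chromosome 4 (6.38), a zinc-finger gene of heart and neural development. Replicate 1 had other promoter peaks at Foxc1 and Casz1 but none at Plbd1. For comparison, the complete lists of replicates 1 and 2 had median enrichments of 2.93 and 3.19 and reached 45.0 and 54.6.

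**Figure D1:**
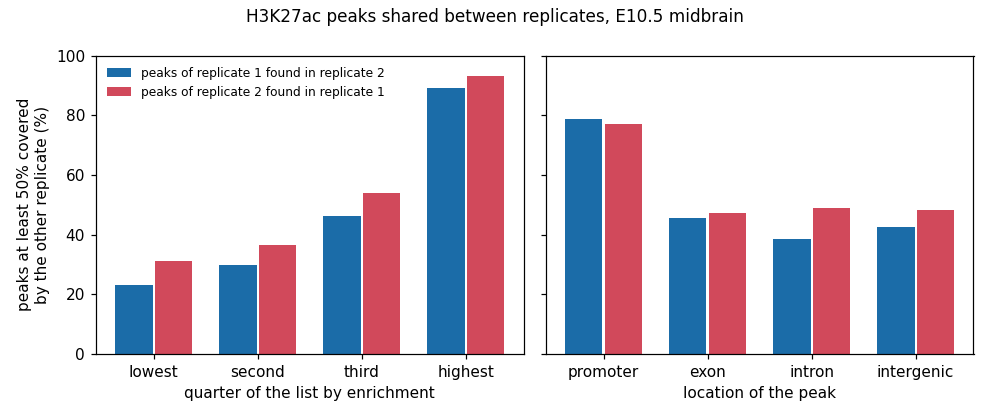
Percent of peaks of each replicate that were at least 50% covered by peaks of the other (vertical axis), by quartile of the list ranked on the authors' enrichment (left) and by location (right); blue bars are replicate 1 peaks and red bars replicate 2 peaks. The share rose from 23.2% and 31.0% in the lowest quartile to 89.3% and 93.1% in the highest, and promoter peaks were shared most often (78.6% and 76.9%).

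The replicated list was then set against the pooled list, to describe what it holds. All 86424 replicated peaks were pooled peaks with the same coordinates and enrichment, and they made up 48.4% of the pooled list. Promoter peaks formed 22.6% of the kept peaks and 6.77% of the others, and kept peaks had medians of 596 bp and 3.28-fold enrichment against 215 bp and 2.31-fold. The share kept rose with enrichment from 8.75% in the lowest quartile of the pooled list to 99.2% in the highest. Of the kept peaks, 82.4% overlapped a peak of each replicate by at least 50% of either peak, and 0% of the 91994 other peaks did. The remaining kept peaks did not meet this overlap, so the list was not limited to positions called in both replicates.

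H3K27ac was concentrated at promoters, the 1 kb on either side of annotated transcription start sites. Promoters took 22.6% of the replicated peaks (19503 peaks; 95% Clopper-Pearson interval 22.3 to 22.8), 3.49 times the 6.46% ± 0.0834 of shuffled peaks. Introns took 39.5% against 36.8% shuffled, exons 8.89% against 8.03%, and intergenic sequence 29.0% against 48.7%. Promoter peaks had a median width of 1298 bp and a median enrichment of 9.24, while intronic peaks had 500 bp and 3.04, so promoters held 37.4% of the covered sequence. In the lists of the replicates, promoters took 17.3% ± 0.594 of peaks (SD, n = 2). In the quartile of the list with the highest enrichment 59.99% of peaks lay at promoters, against 7.99% in the lowest, and in the pooled list as a whole 14.4%.

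Of 21911 protein-coding genes, 14349 (65.5%) had a replicated peak at a promoter; the replicates gave 66.9% ± 1.38 (SD, n = 2). CpG-rich promoters carried the mark most often: in quintiles of promoters ranked by CpG observed over expected, 10.2%, 39.9%, 84.2%, 95.4% and 97.6% had a peak. Promoter peaks of the gene lists were therefore compared both with all other genes and with random lists of the same promoter CpG content. The length of peak sequence, below, was compared only with random lists drawn from all protein-coding genes, without matching on CpG.

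Every member of the midbrain and isthmus, progenitor and neurogenesis lists had the mark at 1 or more annotated start sites. All 26 genes of midbrain and isthmus patterning had a promoter peak, among them the homeobox genes En1, En2 and Otx2, the paired-box genes Pax2, Pax5 and Pax7, and the signals Wnt1 and Fgf8 that pattern the region. These peaks differed in strength, from 17436 bp at 39.6-fold enrichment for Otx2 to weak ones. Pax2 counted through 658 bp at 4.58-fold and Fgf8 through 760 bp at 4.41-fold, against a median of 9.24 for all promoter peaks. Helt counted through a peak at 3.23-fold and had no promoter peak in replicate 2. The 26 neural progenitor genes, such as Sox2, Notch1 and Msi1, all had a promoter peak too. So did the 25 genes of neurogenesis and early neurons, such as Nhlh1 and the proneural genes Ascl1 and Neurog1. Against 65.4% of other genes, the odds ratio, with 0.5 added to each count because no member lacked a peak, was 28.0 for midbrain and isthmus and for progenitor genes (adjusted p = 1.33e-04 each, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 14 lists) and 26.9 for neurogenesis genes (adjusted p = 1.47e-04, Fisher's exact test). Over 9 alternatives the midbrain and isthmus odds ratio ranged from 4.35, in the top quartile of enrichment, to 29.1, with 11.8 in the list of replicate 2. The 25 housekeeping genes, such as Tuba1b, Vcp and Rpl13a, gave the same count and test result as neurogenesis genes. Random lists matched on promoter CpG averaged 88.6% for midbrain and isthmus, 89.9% for progenitor, 83.3% for neurogenesis and 88.9% for housekeeping genes. Against these, only the neurogenesis list stayed past the threshold (adjusted p = 0.0257, permutation test). The midbrain and isthmus, progenitor and housekeeping lists gave an adjusted p of 0.0987 each in the permutation test. This split does not rank the lists, because all members had a peak and no higher count was possible. Even so, the unadjusted p (permutation test) was 0.0512 for midbrain and isthmus, 0.0448 for progenitor and 0.0293 for housekeeping genes. It was 0.0040 for neurogenesis genes, whose matched lists had the lowest mean of these. The test therefore could not decide whether the other lists were marked beyond CpG.

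The Hox genes, which pattern the hindbrain and trunk behind the midbrain, mostly lacked the mark. Of 30 Hox and hindbrain genes 3 had a promoter peak, namely Hoxa1 and the hindbrain segment genes Egr2 and Mafb; Hoxa2, Hoxa10 and Hoxa13 were among those without. The odds ratio was 0.0584 (adjusted p = 5.51e-09, Fisher's exact test), and CpG-matched lists averaged 85.4% (adjusted p = 0.00140, permutation test). Genes of a Hox cluster are neighbours and are not independent of each other.

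Lists for neighbouring brain regions and later midbrain fates were mixed. Of the floor plate and dopaminergic genes 15 of 20 had a promoter peak (odds ratio 1.58, adjusted p = 0.520, Fisher's exact test). Regulators of the early floor plate such as Foxa1, Foxa2 and Shh carried it. Ddc, the aromatic amino acid decarboxylase, counted through a weak peak of 439 bp at 3.77-fold enrichment, against 6780 bp at 17.8-fold for Foxa1. The Ddc peak (11889262 to 11889700) lay within the gene, away from its 5′ end at 11898144. The genes without a replicated peak were Aldh1a1, Arx, Pitx3, Th, the rate-limiting enzyme of dopamine synthesis, and Slc6a3, the dopamine transporter; Th and Slc6a3 were added to the named genes after their values were seen. Arx and Th had a promoter peak in replicate 1 alone and Slc6a3 in replicate 2 alone. Of the forebrain and eye genes 18 of 23 had a peak (odds ratio 1.90, adjusted p = 0.382, Fisher's exact test), including Emx1, Lhx2 and Six3, and Eomes, Six6 and Tbr1 did not. Against CpG-matched lists both odds ratios fell below 1, to 0.572 and 0.407, as they did in the top quartile of enrichment (0.965 and 0.421), without passing the threshold.

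Lists of markers of other tissues were mixed, and several depended on the replicate. Neural crest and head mesenchyme genes had a peak in 20 of 23 cases (odds ratio 3.52, adjusted p = 0.0506, Fisher's exact test); Prrx2, Sox10 and Pdgfrb carried it, and the extracellular matrix genes Dcn and Lum and the crest regulator Foxd3 had none in the replicated list. Dcn had one in both replicates' own lists and Foxd3 in that of replicate 2. The lists of the replicates held 18 and 22 of these 23 genes, and the odds ratio was 21.1 in the pooled list, with 0.5 added to each count (adjusted p = 7.47e-04, Fisher's exact test), 10.4 in the list of replicate 2 (adjusted p = 0.00546, Fisher's exact test) and 0.421 in the top quartile of enrichment. Endothelial genes had 11 of 18 (odds ratio 0.828, adjusted p = 0.805, Fisher's exact test), with 11 in replicate 1 and 16 in replicate 2, where the odds ratio was 3.79. Egfl7 and Eng carried the mark, while Esam, Etv2 and Plvap lacked it in the replicated list. Esam and Plvap had it in replicate 2. Surface ectoderm genes had 6 of 14 (odds ratio 0.395, adjusted p = 0.143, Fisher's exact test), with 6 in replicate 1 and 11 in replicate 2, where the odds ratio was 1.74. Cdh1 and Krt8 carried it, and Cldn4, Cldn6 and Esrp1 had it in replicate 2 alone. Against CpG-matched lists this list was low (72.4% on average, adjusted p = 0.0257, permutation test). In the top quartile of enrichment endothelial (odds ratio 0.158, adjusted p = 0.00210) and surface ectoderm genes (0.215, adjusted p = 0.0183) passed as low in Fisher's exact test.

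Erythroid genes had a promoter peak in 10 of 18 cases (odds ratio 0.659, adjusted p = 0.520, Fisher's exact test), with Nfe2, Slc4a1 and Epor among them and Alas2, Gata1 and Hba-a1 without. Heart and skeletal muscle genes had 11 of 20 (odds ratio 0.644, adjusted p = 0.446, Fisher's exact test); Tnnt3 and Tnni1 carried it and Acta1, Ckm and Gata4 did not. For both lists the odds ratio against CpG-matched lists lay above 1, at 1.70 and 1.25. In the top quartile of enrichment both passed as low, at 0.303 and 0.0415 (adjusted p = 0.0232 and 7.15e-06, Fisher's exact test). Microglia and macrophage genes had 5 of 15 (odds ratio 0.263, adjusted p = 0.0258, Fisher's exact test); C1qb carried it and C1qa, C1qc and Cd68 had none in the replicated list. Cd68 had one in both replicates' own lists and C1qc in that of replicate 1. That call ended in the lists of the replicates, with 8 of 15 in each and odds ratios of 0.590 and 0.540, in the pooled list (0.671), with promoters of 2.5 kb either side (0.426) and against CpG-matched lists (adjusted p = 0.579, permutation test). Liver genes had 4 of 18 (odds ratio 0.150, adjusted p = 5.13e-04, Fisher's exact test), with Foxa3 and Hnf1a among them and Afp, Ahsg and Alb, the genes of fetal and adult serum proteins, without. The liver call ended against CpG-matched lists (42.0% on average, adjusted p = 0.0987, permutation test) and with promoters of 2.5 kb either side (odds ratio 0.389).

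**Figure D2:**
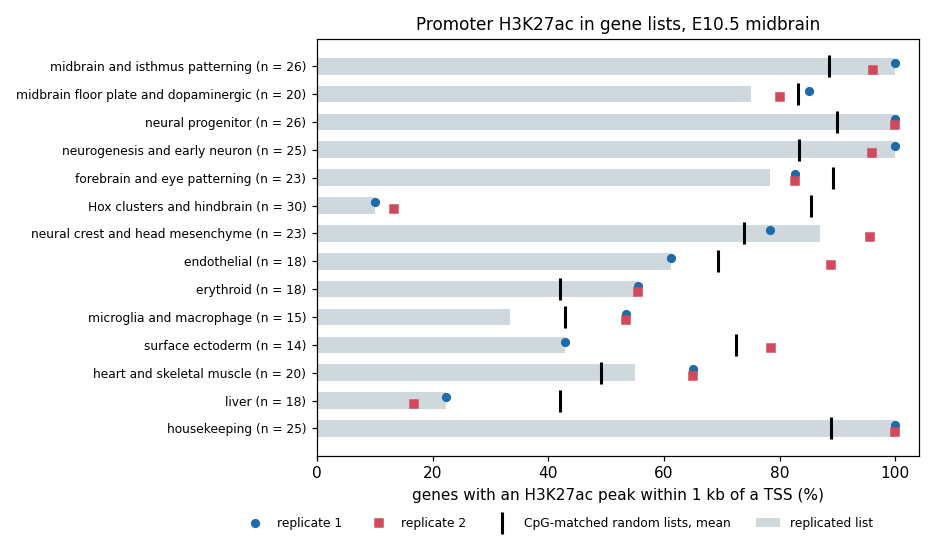
Percent of the genes of each list with an H3K27ac peak within 1 kb of an annotated transcription start site (horizontal axis); grey bars show the replicated list, blue circles and red squares the lists of replicates 1 and 2, and black lines the mean of random lists matched on promoter CpG. Midbrain and isthmus, progenitor, neurogenesis and housekeeping genes reached 100%, Hox and hindbrain genes 10%, and endothelial and surface ectoderm genes were higher in replicate 2 (88.9% and 78.6%) than in replicate 1 (61.1% and 42.9%).

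Beyond promoters, the length of sequence under peaks within 50 kb of each gene's 5′ end was compared between lists. Midbrain and progenitor genes had the highest means of the 14 lists. En2, the engrailed gene of the midbrain and anterior hindbrain (chromosome 5, 28165694 to 28172166), had 45.6 kb of peaks around it (42.5 ± 3.30 kb in the replicates, SD, n = 2), En1 had 32.6 kb (31.1 ± 1.99) and Pax7, a gene of the dorsal midbrain, 30.8 kb (29.2 ± 3.64). Otx2, which specifies forebrain and midbrain and was added to the named genes after its values were seen, had 29.5 kb, with a promoter peak of 17436 bp at 39.6-fold enrichment. Among progenitor genes Notch1 had 58.4 kb (51.8 ± 7.10), Msi1, an RNA-binding protein of neural stem cells, 50.4 kb (46.6 ± 4.11) and Sox2 43.7 kb (42.4 ± 0.922). Midbrain and isthmus genes averaged 18587 bp and progenitor genes 24879 bp, against 6085 bp and 6078 bp for other genes, differences of 3.98 and 4.37 on the log2 scale (adjusted p = 6.53e-04 and 1.40e-04, two-sided permutation test, Benjamini-Hochberg over 14 lists).

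Neurogenesis genes also had more peak sequence around them than other genes. They averaged 11933 bp against 6093 bp, a difference of 3.10 on the log2 scale (adjusted p = 0.00557, permutation test), led by Nhlh1 with 35.2 kb (31.0 ± 5.32), Neurog1 with 27.7 kb (25.3 ± 2.58) and Ascl1 with 20.9 kb (19.6 ± 2.70). Housekeeping genes averaged 12297 bp with a difference of 3.22 (adjusted p = 0.00493, permutation test), led by Tuba1b with 30.9 kb, Vcp with 22.8 kb and Rpl13a with 21.8 kb. The difference was 2.05 for floor plate and dopaminergic genes (adjusted p = 0.103, permutation test), where Ddc had 24.7 kb (21.7 ± 1.66), Foxa2 21.99 kb (20.1 ± 3.68) and Foxa1 18.5 kb (16.3 ± 2.01). Aldh1a1 had 0 kb, Arx 2.20 kb and Pitx3, which is required for dopaminergic neurons, 3.40 kb. This list passed within 20 kb (2.54, adjusted p = 0.0478) and with distal peaks alone (3.02, adjusted p = 0.0231) in the permutation test. In the top quartile its difference was 0.446. Forebrain and eye genes did not pass (1.92, adjusted p = 0.103, permutation test), and their longest values were 12.2 kb at Emx1, 12.02 kb at Lhx2 and 11.1 kb at Six3. Without the log scale the forebrain difference from other genes was -884 bp.

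Around Hox and hindbrain genes there was little acetylation. The list averaged 495 bp against 6108 bp, a difference of -5.83 on the log2 scale (adjusted p = 1.40e-04, permutation test), and its longest values were 3.75 kb at Egr2, 3.69 kb at Mafb and 1.48 kb at Hoxa1. From Hoxa1 to Hoxa13 and 20 kb beyond on each side (chromosome 6, 52135590 to 52280880), the replicated list held 1 peak, of 370 bp at 2.70-fold enrichment beside Hoxa1 (52158456 to 52158825), while 126 kb around En2 held 18 peaks over 45.6 kb. The Hox difference was -2.43 in the list of replicate 2 and -2.34 within 100 kb. When 1 member was kept per 100 kb, a step chosen after the data were seen that left 8 members, the difference was -2.33 and the call ended (adjusted p = 0.298, permutation test).

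**Figure D3:**
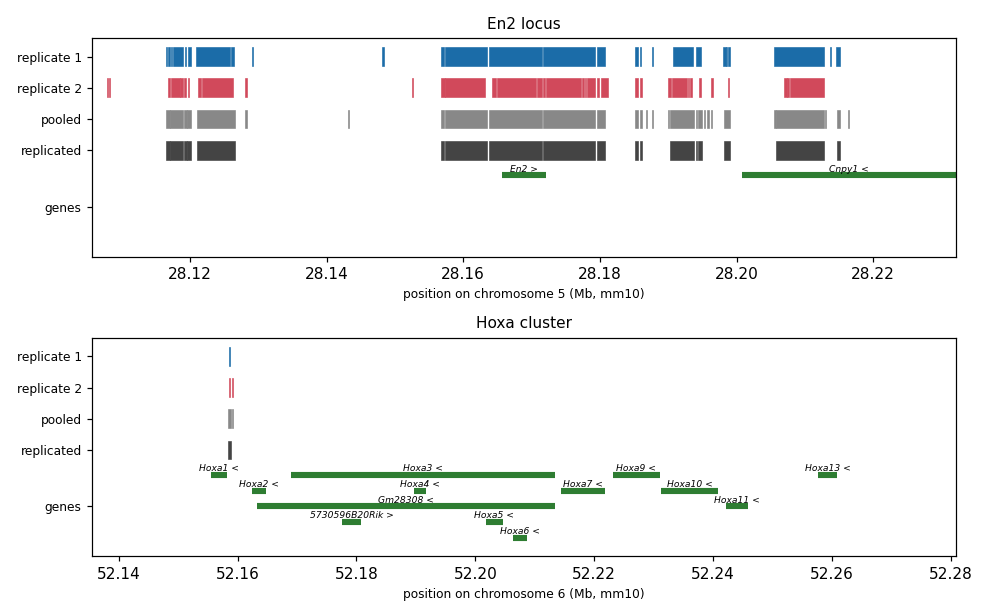
Peaks of the lists of replicate 1 (blue), replicate 2 (red), both replicates pooled (light grey) and the replicated list (dark grey) on chromosome 5 around En2 and on chromosome 6 over the Hoxa cluster, with protein-coding genes in green and their strand as > or <; the horizontal axes give the position in Mb on mm10. Replicated peaks covered 45.6 kb of 126 kb around En2 and 0.370 kb of 145 kb over Hoxa.

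Of the lists for other tissues, microglia and macrophage genes were the only one past the threshold. The complement genes C1qb, C1qc and C1qa had 34.6 kb (30.7 ± 5.55), 29.3 kb (26.3 ± 4.78) and 26.7 kb (25.1 ± 3.06) around them. These are neighbours on chromosome 4 next to Ephb2, an ephrin receptor of the developing brain, in the same stitched domain. The list differed by 3.10 on the log2 scale (adjusted p = 0.0282, permutation test). The call ended with 1 member per 100 kb (2.81, adjusted p = 0.0883, permutation test), within 20 kb (2.12) and in the top quartile of enrichment (1.35). With distal peaks alone the difference was 5.75. Endothelial genes differed by 2.09 (adjusted p = 0.103, permutation test), with 35.2 kb at Egfl7 (30.9 ± 1.21), whose window overlaps that of its neighbour Notch1, 28.1 kb at Eng, a co-receptor for TGF-beta, and 17.0 kb at Plvap. Surface ectoderm genes differed by 1.18 (adjusted p = 0.483, permutation test), with 16.7 kb at Cdh1, the epithelial cadherin, 15.2 kb at Grhl3 and 9.03 kb at Krt8. With distal peaks alone endothelial and surface ectoderm genes passed, at 3.67 and 3.98 (adjusted p = 0.0106 and 0.0113, permutation test), while in the top quartile of enrichment the endothelial difference was -1.43.

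The remaining lists did not pass the test. Neural crest and head mesenchyme genes differed by 0.56 on the log2 scale (adjusted p = 0.688, permutation test), with 23.8 kb at Prrx2, 20.8 kb at Sox10 and 14.6 kb at Pdgfrb, and Dcn, Foxd3 and Lum at 0 kb. Their difference was -1.40 in the top quartile of enrichment, 1.62 in the pooled list and 1.77 in the list of replicate 2, and passed in none of these. Erythroid genes differed by -0.21 (adjusted p = 0.859, permutation test), with 24.8 kb at the transcription factor Nfe2, 20.2 kb at Slc4a1, the anion exchanger of red cells, and 10.9 kb at Epor; in the list of replicate 2 the difference was 1.51. Heart and skeletal muscle genes differed by 1.15 (adjusted p = 0.419, permutation test), with 50.9 kb at Tnnt3, 18.4 kb at Myh6 and 15.4 kb at Tnni1, and by -0.28 in the top quartile. Liver genes differed by -0.43 (adjusted p = 0.769, permutation test), with 22.3 kb at Apoa2, 11.9 kb at Foxa3 and 6.73 kb at Hnf1a, and by 1.77 with distal peaks alone. Peaks of any neighbouring gene count within a window, so a length belongs to a neighbourhood and not to the named gene alone.

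**Figure D4:**
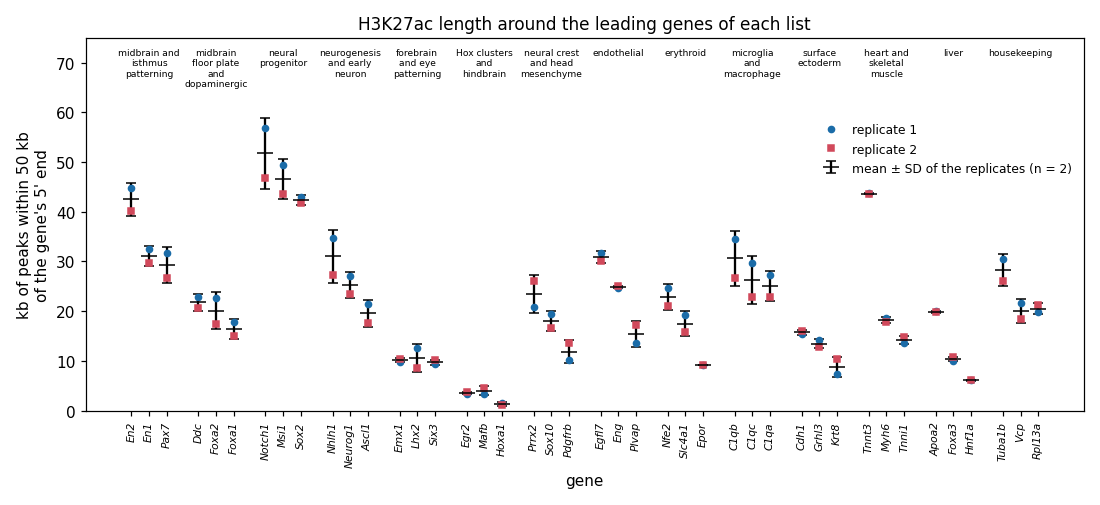
Kilobases of H3K27ac peaks within 50 kb of the 5′ end of the 3 leading genes of each list (vertical axis); blue circles and red squares are the lists of replicates 1 and 2, and black bars their mean ± SD (n = 2). Notch1, Msi1, Sox2, En2 and Tnnt3 lay above 40 kb on average, and Egr2, Mafb and Hoxa1 were the lowest leading genes.

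Among the 10 widest peaks were those of Sox2, Pou3f2 and Pou3f3, members of the progenitor list. A 24.5 kb peak on chromosome 2 (18036695 to 18061214; 24.4 ± 0.110 kb covered in the replicates, SD, n = 2) spanned start sites of Skida1, Mllt10 and A930004D18Rik. Sox2 lay in a 24.3 kb peak (24.3 ± 0.0544; chromosome 3, 34647877 to 34672226), and the POU-domain genes Pou3f2 and Pou3f3 in peaks of 24.0 kb (23.7 ± 0.441; chromosome 4, 22476173 to 22500215) and 19.2 kb (18.9 ± 0.346; chromosome 1, 42683661 to 42702824). Bahcc1, a chromatin protein gene, had 23.8 kb (23.2 ± 0.665; chromosome 11, 120221541 to 120245346). Over Nr2f2, an orphan nuclear receptor gene, a 21.5 kb peak lay 2.59 kb from its annotated 5′ end (chromosome 7, 70342657 to 70364149). Id3, an inhibitor of bHLH factors, had 18.3 kb (chromosome 4, 136131318 to 136149568) and Zeb2, a zinc-finger homeobox gene, 18.1 kb (chromosome 2, 45099800 to 45117866). The other two lay on chromosome 2 away from coding promoters: 19.1 kb (30644200 to 30663292), 49.2 kb from Cstad, and 17.6 kb (29842001 to 29859578) over the microRNA gene Mir219a-2, 9.59 kb from Cercam.

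When peaks at most 12.5 kb apart were stitched, they formed 28179 domains, of which 14435 held a single peak, and the domain with the most covered sequence lay at Zfp36l1, a gene for an mRNA-decay factor (280 kb under 222 peaks; 242 ± 31.2 kb in the replicates, SD, n = 2; chromosome 12, 79591432 to 80151261). Gins2, a replication factor gene (260 kb; 224 ± 37.9), Mn1 (229 kb; 200 ± 34.1), Msi2, the paralogue of Msi1 (216 kb; 192 ± 46.1), and Vezf1 with Mrps23 and Ccdc182 (171 kb; 153 ± 13.9) followed. Cstad had 161 kb, Trp53i11 and Tspan18 140 kb, the cluster from Cacna2d2 to Sema3f 139 kb, Ccdc85c 128 kb, the cluster from Tmem209 to the imprinted gene Mest 126 kb and Zfp423, a zinc-finger gene of midline brain development, 115 kb. Srgap3 (114 kb), Ephb2 with the C1q genes (113 kb), Tfeb with Foxp4 (112 kb), Kif26a (107 kb), the cluster from Sbno2 to Dazap1 (102 kb), Slc38a10 with Bahcc1 (100.1 kb), a domain 20.3 kb from Zfp36l2 (99.8 kb), Zbtb16 (97.8 kb) and Ncor2 (94.2 kb) completed the 20 domains with the most covered sequence. The ranking depended on the stitching: 13 of the 20 were touched by the top 20 at 5 kb, and 3 by the 20 widest unstitched peaks.

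Of the 10 genes with the most peak sequence within 50 kb, all but Flrt1 lay in these domains. Efna2, an ephrin ligand gene, had 74.8 kb (67.2 ± 6.49 in the replicates, SD, n = 2), and its neighbours on chromosome 10 Cirbp, a cold-inducible RNA-binding protein, 1600002K03Rik and Midn had 71.7 kb (64.3 ± 6.93), 70.8 kb (63.3 ± 6.65) and 61.8 kb (55.1 ± 5.74). Ccdc85c had 66.9 kb (58.5 ± 2.76), Ccdc182 66.5 kb (60.7 ± 10.4), Bahcc1 65.4 kb (59.0 ± 4.29), Cpa1 64.5 kb (52.9 ± 3.95), Flrt1 63.1 kb (54.0 ± 3.11) and Mrps23 61.7 kb (54.2 ± 3.52). For each of these 10 genes the value in the replicated list was above the mean of the replicates.

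Consensus sequences of transcription factors were counted in the 200 bp around the summits of distal peaks, which have no start site within 2.5 kb, to ask which factors' sites go with distal H3K27ac in the midbrain. E-boxes and ZIC and SOX sites were more frequent at summits than 2 kb outside the peak. The E-box CAGCTG, read by bHLH factors such as Ascl1, occurred at 18.5% of summits and in 8.89% of control windows, and 2.34 times as many of the 53807 pairs had it at the summit alone as in the control alone. The ZIC consensus, read by the zinc-finger factors Zic1, Zic2 and Zic5, occurred at 12.5% and 5.26% (ratio 2.61), and the extended SOX consensus, read by Sox2 and its relatives, at 9.67% and 6.05% (1.66). TEAD (1.19), the E-box CAGATG (1.14) and the short SOX consensus (1.07) were higher by less; the largest adjusted p of these 6 was 3.30e-06 (two-sided exact McNemar test, Benjamini-Hochberg over 18 motifs). The TEAD call ended in the top quartile of enrichment (1.13, adjusted p = 0.0580, exact McNemar test), as did that of CAGATG (1.04). GC content was 53.4% at summits and 45.0% in control windows.

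AT-rich consensus sequences were less frequent at summits than in those control windows, but this depended on the control. The homeodomain consensus TAATTA had a ratio of 0.405, POU 0.501, OTX 0.569, LEF/TCF, which mediates WNT signals, 0.770, GATA 0.801, FOXA 0.821 and the insulator factor CTCF 0.484 (largest adjusted p 0.00128, exact McNemar test). The reversed consensus, a control of composition, was also less frequent for TAATTA (0.370), GATA (0.603), LEF/TCF (0.607), FOXA (0.664) and OTX (0.740), as it was for SOX (0.798) and CAGATG (0.585). NFI (2.25), ETS (1.52), RFX (1.47), REST (1.24) and AP-1 (1.05) did not pass (adjusted p from 0.0515 to 0.165, exact McNemar test). NFI and ETS passed in the central 500 bp (2.71 and 1.58) and against controls 5 kb away (2.83 and 2.39), and RFX in 500 bp (2.56). In the replicates' own lists RFX (1.81) and AP-1 (1.07) passed in replicate 1, ETS (2.23) in replicate 2 and REST in both (1.24 and 1.28). With control windows of the same GC and CpG content, chosen after the data were seen (27303 pairs), SOX extended (2.09), SOX (1.66), CAGCTG (1.42), ZIC (1.38) and TEAD (1.20) were higher at summits, and the call of CAGATG ended (1.03, adjusted p = 0.260, exact McNemar test). TAATTA (1.21), GATA (1.23), FOXA (1.31) and LEF/TCF (1.24) were then higher as well, and OTX (0.727) and CTCF (0.189) lower. The reversed consensus gave 1.23 for TAATTA, as high as the consensus itself, 1.17 for FOXA, 1.24 for SOX, 1.15 for OTX and 0.630 for CAGATG (largest adjusted p 0.00271, exact McNemar test), and did not pass for GATA and LEF/TCF. For SOX extended the reverse, which can hold a CpG, was also raised, at 1.38 (adjusted p = 3.50e-14, exact McNemar test), below the 2.09 of the consensus. When both windows also held at most 10% repeat sequence (13124 pairs), OTX turned to higher as well, at 5.68% of summits against 4.57% of controls (ratio 1.26, adjusted p = 1.48e-04, exact McNemar test), and TEAD (1.08, adjusted p = 0.222) and GATA (1.18, adjusted p = 0.0594) did not pass the exact McNemar test. The reversed consensus there gave 1.11 for OTX (adjusted p = 0.174, exact McNemar test) and 1.26 for TAATTA (adjusted p = 0.0147, exact McNemar test), against 1.38 for TAATTA itself. For SOX extended it gave 1.24 (adjusted p = 0.00334, exact McNemar test), against 1.86 for the consensus. The CTCF ratio was 0.286 there, from 4 against 14 windows (adjusted p = 0.0594, exact McNemar test), 2.83 when the central 500 bp were searched, and 0.883 and 0.778 in the lists of replicates 2 and 1, where it did not pass. A consensus match is not a bound site, and the factors of a family share their consensus.

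**Figure D5:**
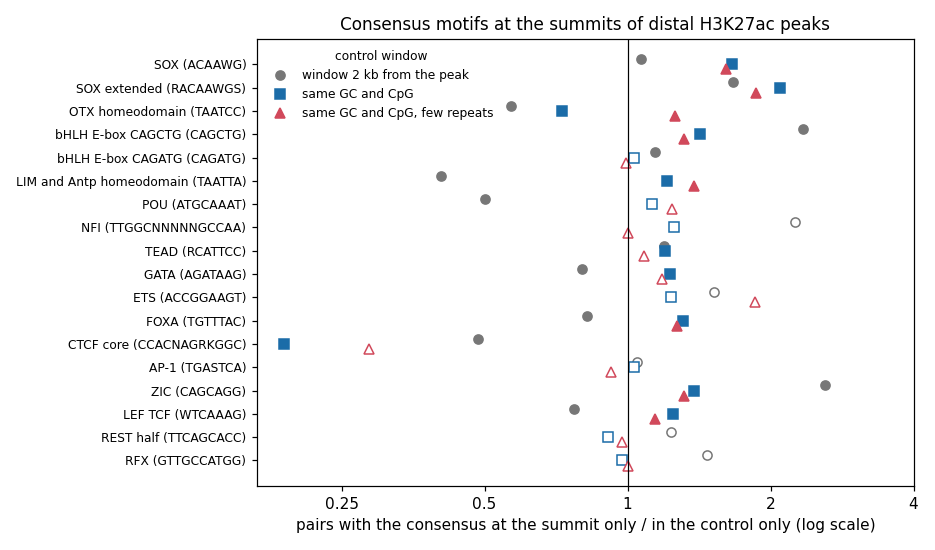
Ratio of pairs with a consensus at the distal summit alone to pairs with it in the control window alone (horizontal log axis; 1 means equal) for 18 motifs; grey circles use control windows 2 kb outside the peak, blue squares controls of the same GC and CpG, and red triangles also at most 10% repeats in both windows, with filled symbols for adjusted p under 0.05 in the exact McNemar test. SOX, CAGCTG and ZIC lay above 1 with all 3 controls, and OTX moved from 0.569 to 1.26.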

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

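Peaks outside the assembled chromosomes, which no comparison used except the match of replicated with pooled peaks, were above the 3 peaks that a count of 0 allows: the replicated list held 9 on 6 unplaced or unlocalised contigs, and the lists of replicates 1 and 2 held 10 each. The strongest, at 37.0-fold enrichment, was 1 of 2 on a contig assigned to chromosome 4 (2618 bp in all), and a contig assigned to the X chromosome held 3 peaks with up to 6.40-fold enrichment. The annotation used here places no gene list member there, and no explanation was tested.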

How the results depend on the processing

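Of 434 values recomputed for 57 results, 327 kept their direction and their side of the threshold (for counts, moved by at most 1.5 times; for percents, by less than the SD or within the 95% interval), 21 no longer passed, 21 newly passed, 24 moved and 41 changed direction; the cause was not tested unless given. All alternatives were planned except control windows matched on GC and CpG, these with few repeats, and 1 list member per 100 kb, which were chosen after the data were seen. In all 9 alternatives for promoters the Hox list stayed low (odds ratio 0.0218 to 0.0725) and the neurogenesis list high (5.80 to 30.2), and in all 10 for length the midbrain, progenitor, neurogenesis and housekeeping lists stayed high. None of these 10 matched the lists on promoter CpG. By construction the quartile of highest enrichment held 35749, 34750, 45589 and 21634 peaks of the replicate 1, replicate 2, pooled and replicated lists. The shared percent of replicate 1 and of replicate 2 was 57.8 and 62.6 at 1 bp, 54.6 and 59.8 at 25%, 35.7 and 36.8 at a reciprocal 50%, and 47.7 and 60.2 with -log10 q of at least 2; pooled peaks touched by both replicates made up 40.7% at 1 bp against 31.2%. The promoter percent of peaks was 14.4 in the pooled list, 59.9 in the top quartile, 16.8 to 17.7 without a replicate, 20.4 with 0.5 kb and 28.7 with 2.5 kb either side. Promoter odds ratios against CpG-matched lists were 6.84 for midbrain and isthmus, 5.92 for progenitor, 6.40 for housekeeping, 0.700 for microglia and 0.428 for liver genes, which no longer passed, 0.292 for surface ectoderm, which newly passed, and 0.572 for dopaminergic, 0.407 for forebrain, 1.70 for erythroid and 1.25 for muscle genes, which changed direction. The midbrain and isthmus, progenitor and housekeeping lists had a peak at every member, so no higher count was possible in that matched test. In the top quartile the promoter odds ratios were 0.965 for dopaminergic, 0.421 for forebrain and 0.421 for crest genes, now below 1. Those of endothelial (0.158), erythroid (0.303), ectoderm (0.215) and muscle genes (0.0415) newly passed there. In the pooled list they were 21.1 for crest (newly passed), 3.58 for endothelial and 1.12 for ectoderm genes (now above 1) and 0.671 for microglia. With 2.5 kb either side microglia (0.426) and liver (0.389) no longer passed. Without a replicate the odds ratio ranged from 1.86 to 10.4 for crest (newly passed without replicate 1), 0.812 to 3.79 for endothelial, 0.387 to 1.74 for ectoderm and 0.540 to 0.590 for microglia genes. Length differences newly passed for dopaminergic genes within 20 kb (2.54) and with distal peaks (3.02), and with distal peaks for endothelial (3.67) and ectoderm genes (3.98). Those of microglia genes no longer passed in the top quartile (1.35), within 20 kb (2.12) and with 1 member per 100 kb (2.81), nor that of Hox genes with 1 member per 100 kb (-2.33, fewer members). Directions changed for crest (-1.40), endothelial (-1.43) and muscle genes (-0.28) in the top quartile, for liver genes with distal peaks (1.77), and without the log for forebrain (-884 bp), crest (-177 bp) and ectoderm genes (-375 bp); for erythroid genes the difference was 0.96 in the pooled list, 623 bp without the log, 0.60 with distal peaks, 1.60 with 1 member per 100 kb and -0.24 to 1.51 without a replicate. Of the 20 domains with the most covered sequence 13 were touched by the top 20 at 5 kb and 3 by the 20 widest unstitched peaks. In the central 500 bp 10 motifs were higher, against 6. Control windows matched on GC and CpG left 2 motifs lower, and with few repeats 0 by the exact McNemar test (1 at an unadjusted p under 0.05), against 7. NFI newly passed in 500 bp (2.71) and against controls 5 kb away (2.83), ETS in both (1.58 and 2.39) and without replicate 1 (2.23), RFX in 500 bp (2.56) and without replicate 2 (1.81), REST without either replicate (1.28 and 1.24) and AP-1 without replicate 2 (1.07). TEAD no longer passed in the top quartile (1.13) and with few repeats (1.08), CAGATG in the top quartile (1.04) and in matched windows (1.03), and CTCF with few repeats (0.286) and without a replicate (0.778 to 0.883). Ratios changed direction in matched windows for TAATTA (1.21), POU (1.13), GATA (1.23), FOXA (1.31), LEF/TCF (1.24), REST (0.908) and RFX (0.971), and with few repeats for OTX (1.26), CAGATG (0.994), TAATTA (1.38), POU (1.24), GATA (1.18), FOXA (1.27), AP-1 (0.923), LEF/TCF (1.14) and REST (0.974); AP-1 was at 0.898 in the top quartile and CTCF at 2.83 in 500 bp. No paired analysis was possible because the labels give 1 group. Unknown read depth limits all lists, since a missing peak can mean too few reads.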

Other observations

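The signalling pathways and microRNAs below, the list members in the largest domains and the tests of general calling and of base composition were chosen after results had been seen; the other tests were written down before their values were known. Genes of the Hedgehog, Notch, BMP, WNT and FGF pathways had on average more peak sequence around them than other genes. Housekeeping genes, with 12297 bp and a difference of 3.22, lay within the range of these pathways. The lists were not matched on promoter CpG, and single members lay low, such as Dkk1 at 0.899 kb and Grem1 at 0.814 kb. Within 50 kb, Hedgehog pathway genes averaged 15.4 kb of replicated peaks, a difference of 3.62 on the log2 scale from other genes (adjusted p = 0.0221, permutation test over 9 lists), led by the receptors Boc (34.1 kb), Ptch1 (27.5 kb) and Cdon (19.0 kb). Notch pathway genes averaged 14.6 kb (2.64, adjusted p = 0.0265, permutation test), led by Lfng (51.0 kb), a modifier of Notch receptors, and the feedback inhibitor Nrarp (38.2 kb), and BMP pathway genes 13.7 kb (2.93, adjusted p = 0.0205, permutation test), led by the target genes Id3 (51.2 kb), Id1 (33.1 kb) and Id2 (31.0 kb). WNT pathway genes averaged 12.8 kb (3.24, adjusted p = 0.0205, permutation test), with the feedback inhibitor Axin2 at 37.7 kb, and FGF pathway genes 10.4 kb (3.05, adjusted p = 0.0265, permutation test), with Fgfr3 at 31.5 kb. Cell cycle genes averaged 11.4 kb (3.10, adjusted p = 0.0205, permutation test), with Mcm2 at 34.9 kb. Genes of later stages passed too: synaptic genes averaged 10.5 kb (2.44, adjusted p = 0.0265, permutation test), led by Camk2a at 37.8 kb, and glial genes 8.46 kb (2.79, adjusted p = 0.0221, permutation test), led by the myelin gene Mbp at 20.7 kb, although glial genes did not pass for promoter peaks (14 of 19, odds ratio 1.48, adjusted p = 0.630, Fisher's exact test). Retinoic acid pathway genes averaged 13.2 kb but did not pass on the log2 scale, where members with 0 kb weigh heavily (0.66, adjusted p = 0.599, permutation test), with Crabp2 at 44.7 kb and Rara at 39.2 kb but Cyp26a1, Cyp26c1 and Rarb at 0 kb. Rarb nevertheless had a promoter peak, at a start site outside the window around its 5′ end. The same held for Rbpj of the Notch list, also at 0 kb.

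Of 9 neural microRNA genes 8 lay under a replicated peak, against 2 of 8 of other tissues, counts that were not tested. Mir9-3 had 46.2 kb of peaks within 50 kb (39.1 ± 11.95 in the replicates, SD, n = 2), Mir219a-2 45.2 kb (41.996 ± 0.960), Mir9-2 26.2 kb (22.9 ± 7.65) and Mir124a-3 22.5 kb (19.4 ± 2.36), and Mir124a-2 lay in a peak of 15.2 kb with 49.6-fold enrichment; Mir9 and Mir124a are microRNAs of neural progenitors and neurons. The lowest neural ones were Mir128-2, with 4.10 kb, and Mir128-1, with 1.46 kb and no peak over it. Among those of other tissues, the liver microRNA Mir122 had 2.64 kb and the muscle microRNA Mir1a-1 1.81 kb, but the blood-cell microRNA Mir142 had 20.9 kb with no peak over it. The 2 under a peak were Mir144, with 10.3 kb, and Mir206, with 0.592 kb. In the 500 stitched domains with the most covered sequence lay the start sites of 16 of 26 progenitor genes (odds ratio 33.1, adjusted p = 2.24e-14, Fisher's exact test over 14 lists) and 8 of 26 midbrain and isthmus genes (9.12, adjusted p = 1.15e-04, Fisher's exact test). No other list passed, with 4 of 25 housekeeping genes (3.89) and 3 of 15 microglia and macrophage genes (5.11) there (adjusted p = 0.107 each, Fisher's exact test). The neurogenesis list, which had passed the test of length, had 0 of 25 genes there. This is no contrast with other genes, of which 4.68% lay there (p = 0.629 unadjusted, Fisher's exact test).

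Promoters of mesenchyme, endothelial and surface ectoderm markers had peaks more often in replicate 2: of the 14 genes of these lists with a promoter peak in exactly 1 replicate, 14 had it in replicate 2 (100%), 4, 5 and 5 per list. More promoter calls of all kinds in replicate 2 could account for this in part, since 70.6% of other such genes (710 against 296) also had theirs in replicate 2; the lists were higher (p = 0.0141, Fisher's exact test), but they had been picked for that. With the 70000 strongest peaks of each list the share was 93.3% against 73.2% (p = 0.135, Fisher's exact test), which leaves a looser threshold in replicate 2 open. Among 73 further markers of these tissues it was 86.7% (13 against 2; p = 0.254, Fisher's exact test), and with the strongest peaks 73.9% against 73.5% of other genes (p = 1, Fisher's exact test), so more such tissue in the dissected pool of replicate 2 can neither be excluded nor told apart from the calling.

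The X chromosome held few peaks, 6.60 per Mb against 34.6 on autosomes (24.2 to 56.0 over single autosomes), and 1.19 per protein-coding gene against 4.10. Of the CpG-rich promoters on X 91.0% had a peak (182 of 200, 95% interval 86.1 to 94.6) against 96.7% on autosomes (p = 1.89e-04, Fisher's exact test). This gap is small beside the deficit in peaks per Mb and says little about its size. CpG-rich promoters are 21.1% of promoters on X and 41.2% on autosomes, and the effect of that share was not tested. A lack of them cannot be the whole cause, because distal peaks, given below, were also rare on X. Repeats do not account for it either, since the ratio of X to autosomes was 0.242 in peaks per Mb outside repeats. A candidate explanation is that a mixed-sex pool holds fewer active copies of X than of each autosome: the median enrichment of promoter peaks at CpG-rich promoters was 13.2 on X and 19.1 on autosomes, a ratio of 0.689 (p = 0.0001, permutation test, the smallest that 10000 permutations can give). Distal peaks per Mb outside repeats were rarer still on X (6.10 against 38.3, a ratio of 0.159), so this lower enrichment is not shown to account for the size of the deficit, and a mappability limit of short reads beyond masked repeats was not tested.

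The OTX and CTCF consensus sequences were less frequent at distal summits than outside the peaks (0.569 and 0.484), although Otx2 is a main regulator of this tissue. For CTCF this held only close to the summit, with 2.83 in the central 500 bp. It did not pass in the lists of replicates 2 and 1 (0.883 and 0.778). Base composition alone does not account for the lower OTX or CTCF ratio in 200 bp, as windows of the same GC and CpG gave 0.727 and 0.189. For OTX, interspersed repeats that carry the consensus in the control windows may be the cause, since with few repeats in both windows the ratio was 1.26 (unadjusted p = 4.92e-05, adjusted p = 1.48e-04, exact McNemar test); for CTCF it was 0.286 there, from only 4 against 14 windows (unadjusted p = 0.0309, adjusted p = 0.0594, exact McNemar test), which argues against repeats in that single test but does not pass over 18 motifs. In 200 bp windows in the middle of gaps of 100 to 600 bp between neighbouring distal peaks the ratio was 4.2 for CTCF (21 against 5 of 4020 pairs, unadjusted p = 0.00249, adjusted p = 0.0120, exact McNemar test) and 1.24 for OTX (unadjusted p = 0.0225, adjusted p = 0.0676, exact McNemar test). Sites beside the acetylated nucleosomes could give this, although for OTX the ratio was no higher than at summits with few repeats. In gaps under 200 bp the window ran into the flanking peaks. Gap windows were also not cleared of peaks of the other lists, so they were not all free of H3K27ac. RFX (7), POU (1.77) and CAGCTG (1.27) were also raised in the gaps (adjusted p = 0.00438, 0.0120 and 0.00438, exact McNemar test), so the rise is not particular to CTCF, and for OTX both repeats and sites in gaps stay open.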
